A study of Nostoc sp. PCC 7120 = FACHB-418 with 18 samples.

How the data were processed

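Total RNA of a Nostoc (Anabaena) sp. PCC 7120 strain was depleted of ribosomal RNA and made into Illumina libraries, per the labels' extract protocol, from cultures without and with cobalt at 48, 72 and 96 h, in 3 libraries per group. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.2.1 and StringTie 2.2.1, without saying which step each served. The genome build and the strand setting are not given in the sources used here. The authors deposited 1 table of FPKM values, with 6155 genes and a column for each of the 18 libraries. No step between the reads and these values was repeated here. Overlapping and antisense genes could not be told apart, since the strand setting is not stated, and near-identical copies such as the psbA genes are reported as uncertain.

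Libraries were grouped by their titles. Replicate 3 without cobalt at 96 h carries the treatment label of the other condition, and the fits that left out each library in turn cover its removal. Replicates are separate samples per the labels, which do not say that they came from separate cultures, so p-values measure the spread between these samples. No pair of libraries held identical values in more than 0.926% of genes. Depth is unknown. The step sought was that of 1 aligned base, not of a whole fragment. If it were recovered, low FPKM values multiplied by gene length would be whole multiples of it. At the best of many steps tried, only between 35.6% and 75% of the low values were within 0.04 of a whole multiple. For 1 fixed step 8% would be by chance, and the best of many steps gives more. So reads were not recovered and no count test was run. Between 39 and 117 genes were listed at 0 per library, and the transfer-messenger RNA gene ssrA took 11.6% to 18.1% of the FPKM sum.

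Gene names came from a RefSeq table of the assembly ASM970v1, which matched 6127 of the 6155 gene identifiers, 899 of them with a symbol. It was used for names and for which genes neighbour each other, and no coordinates are given. It holds no product names, so the 30 gene lists fixed beforehand were matched by symbol and locus tag. Of these lists 26 had at least 1 matched gene and 24 had the required 4 kept genes. The lists of iron acquisition and of oxidative stress and high light proteins kept 1 gene each and were not tested, and 4 lists had no matched gene.

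FPKM as deposited were transformed to log2(FPKM + 1), a scale that understates the changes of low genes. Genes with a mean under 1 FPKM over all libraries were left out (420 genes) and 5735 were kept. A single limma fit with a mean for each of the 6 groups used all 18 libraries, with an intensity trend in the variance and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. Comparisons were cobalt removal at each time, the difference of that effect between 48 h and the later times, and culture age with cobalt. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists of a time, and again with an estimated correlation and with fry, which asks whether a list's genes moved one way on balance and does not compare them with other genes. Lists can hold neighbouring genes that may be read together, so counts of called members are not counts of independent results. The devH level was tested by an exact permutation of libraries within each time. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

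Named genes were chosen by a rule set beforehand. It took, at each time and in each direction, the 10 largest called changes among genes with a product name, at least 10 FPKM in the higher group and no overlap between the groups' libraries, and the 2 largest of any name. It added 3 genes of each list that passed, the 4 largest differences between times and the 3 largest changes with age in each direction, and 11 fixed genes with devH first. Since the name table gives no products, a gene with a symbol was taken as one with a product name. A symbol that several genes share is given with the locus tag. The gene alr0607, and the effects given for alr0608, alr0610, bchL and nifH (alr0874) at times where the rule did not take them, were named after their values were seen. So were genes outside the rule that the closing sections name for the age-related set, the neighbours of devH and the runs.

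The steps were tested on simulated data drawn for the 5735 genes from the real means and spreads. With 100 genes changed by 1 on the log2 scale, 71%, 86% and 79% were called at 48, 72 and 96 h, and with 100 changed by 0.5, 25%, 25% and 20%. Of the 5486 unchanged genes 0.109%, 0.146% and 0.164% were called. A list shifted by 0.3 was called at each time, with 0 of the 23 other lists. The noise was drawn for each gene on its own, so members of a simulated list were not correlated. For each gene it had the same spread in every library, taken from the fit itself. The share of unchanged genes called is therefore no measure of false gene calls in the real data. In the real data the estimated correlation within a list reached 0.24 (CRISPR-associated genes), so the simulation is no measure of false list calls there.

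Replicate numbers are shared between groups in the labels. At 48 h the deviations of same-numbered libraries from their group means correlated at 0.519, 0.182 and 0.175, each above 0.1, which pairs the 48 h libraries by the rule used here, although other pairings reached 0.24. Correlations were -0.156, 0.299 and 0.0873 at 72 h and 0.666, -0.0231 and 0.116 at 96 h, which did not meet it. The main fit left the libraries unpaired at every time, 48 h included, and blocks by replicate number are among the alternatives. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at 10 FPKM, rescaling to a common sum, median-of-ratios scaling, quantile normalization, a fit of the compared groups alone, a replicate block, array weights, a change of at least 1, the other list tests and leaving out each library. Further choices were made after seeing the data: a block for each replicate number within each time, array weights estimated gene by gene, added because the default estimate gave extreme weights, and a search for runs of at least 5 neighbouring genes called in the same direction, set against 100 shuffles of gene order. Scaling moved the median change of the tested genes from -0.15, -0.09 and -0.14 at 48, 72 and 96 h as deposited to 0.00, 0.01 and 0.01 with median-of-ratios scaling, so list medians are given relative to the median of the tested genes.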

Results

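RNA abundance was measured by RNA sequencing in the filamentous cyanobacterium Nostoc (Anabaena) sp. PCC 7120, in a strain whose gene devH (alr3952) stands under the promoter PcoaT, which is switched on by cobalt or zinc ions. DevH is a DNA-binding regulator of the CRP family known from work on heterocysts, the cells that fix nitrogen. Cultures grown with cobalt were washed and restarted in BG11, a medium that contains nitrate, with or without cobalt, and sampled at 48, 72 and 96 h, per the labels' growth protocol and the series design. Each of the 6 groups held 3 libraries, 18 in all. The values were the deposited FPKM (fragments normalised for gene length and library size) of 6155 genes, of which 5735 were tested. FPKM summed to between 911431 and 998643 per library, the median gene lay between 10.5 and 22.5 FPKM, and the read depth is unknown. Changes below are log2 differences ± SE of FPKM + 1, without cobalt minus with cobalt unless stated, with adjusted p-values from limma. Unless times are compared, rose and fell mean higher and lower without cobalt than with it at the same time. Levels are mean FPKM ± SD over 3 libraries. Replicate 3 without cobalt at 96 h carries a treatment label that reads with cobalt, whereas its title, its column name and the triplicate design place it without cobalt, and it was grouped by its title. No strain with devH under its own promoter was analysed here, so the comparisons describe cobalt removal and the lower devH level together.

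The series design gives removal of cobalt as the means to deplete devH, and the first comparison asked how far the devH transcript fell. At 48 h devH stood at 295.8 ± 32.3 FPKM without cobalt and 600.6 ± 38.1 FPKM with cobalt (SD, n = 3 each). At 72 h the levels were 240.7 ± 19.9 and 973.4 ± 20.7 FPKM, and at 96 h they were 221.4 ± 14.4 and 773 ± 56 FPKM. The change was -1.02 ± 0.0891 at 48 h (adjusted p = 3.5e-07), -2.02 ± 0.0891 at 72 h (adjusted p = 5.39e-11) and -1.80 ± 0.0891 at 96 h (adjusted p = 1.57e-10). Over the 3 times the mean log2 difference was -1.61, with an exact permutation p of 0.00025, two-sided, from 8000 arrangements within each time, the smallest p they can give. The library with the conflicting treatment label held 236.8 FPKM of devH, against 208.3 and 219 FPKM in the other libraries of its group. The transcript was lower in each library without cobalt than in each library with cobalt of the same time, and it remained detectable in all 9 libraries without cobalt.

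**Figure D1:**
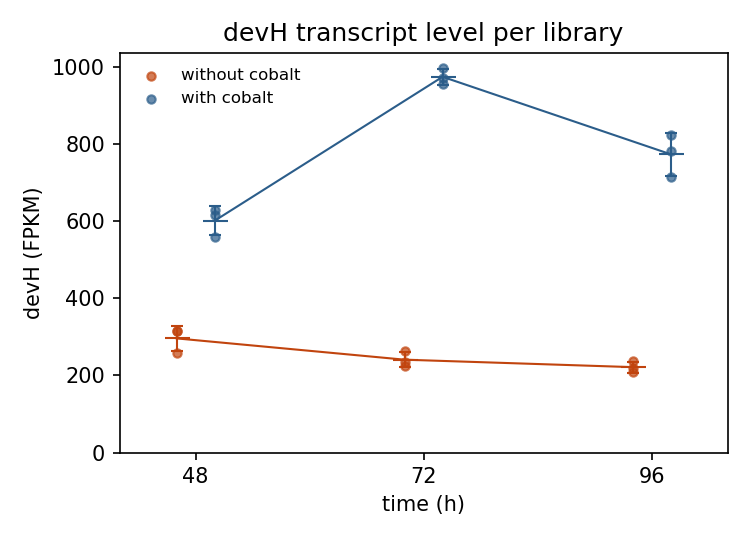
devH transcript level in FPKM (vertical axis, starting at 0) against time in hours (horizontal axis) for cultures without cobalt and with cobalt. Points are libraries, and horizontal marks with bars give the mean and SD of 3 libraries joined by lines. The 48 h means are 295.8 and 600.6 FPKM and the 72 h means 240.7 and 973.4 FPKM.

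At 48 h the largest falls without cobalt lay in genes of the plasmid pCC7120beta. The gene all7607 was at 1.69 ± 0.833 FPKM without cobalt and 365.2 ± 92.1 FPKM with cobalt, a change of -7.10 ± 0.284 (adjusted p = 2.29e-11), and all7598 changed by -6.86 ± 0.314 (adjusted p = 1.23e-10). The sigma factor gene sigB (all7615), on the same plasmid, fell from 73.7 ± 8.29 to 1.09 ± 0.237 FPKM, a change of -5.16 ± 0.157 (adjusted p = 9.93e-13). Genes of response regulators and their sensor kinases fell there too, with rppA (all7606) at -6.22, rppB (all7605) at -4.60, rppA (all7584) at -3.29 and rppB (all7583) at -3.12. The chromosomal rppA (alr1170) changed by -2.05.

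A chromosomal run of neighbouring genes also fell at 48 h, among them folE, thrS and hemB genes whose symbols the name table also gives to another gene each. thrS (all4723), for a threonyl-tRNA synthetase, fell from 41.5 ± 1.32 to 2.83 ± 0.217 FPKM (-3.47 ± 0.108, adjusted p = 1.22e-12). hemB (all4725), for porphobilinogen synthase of heme and chlorophyll synthesis, changed by -3.22, and folE (all4721), for GTP cyclohydrolase, by -3.06. Higher without cobalt were alr1578, at 15.9 ± 0.69 against 1.74 ± 1.02 FPKM (2.71 ± 0.213, adjusted p = 1.02e-07), its neighbour alr1577 (2.66) and vgrG (all3320), whose name is that of a spike protein of contractile injection systems, at 95 ± 5.09 against 25.3 ± 1.55 FPKM (1.87 ± 0.0859, adjusted p = 1.23e-10). Smaller rises were found for lpxB (alr2274, 0.99), the ribosomal protein genes rplD (all4214, 0.93) and rplB (all4212, 0.71), crtH (alr2064, 0.90) of carotenoid synthesis, urtA (all1951, 0.87) of urea uptake, gcvH (all4608, 0.86) of the glycine cleavage system, holA (alr3444, 0.80), rimM (alr2812, 0.73) and purB (alr3395, 0.70). The call of rplD was lost without replicate 2 or 3 without cobalt (adjusted p = 0.0803 and 0.0574) or replicate 1 with cobalt (adjusted p = 0.095). That of lpxB (adjusted p = 0.0394) was lost without any of several libraries (adjusted p up to 0.169), with median-of-ratios scaling (adjusted p = 0.0625) and with quantile normalization (adjusted p = 0.0548).

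Of the genes tested, 1053 changed at 48 h, 266 higher and 787 lower without cobalt, and 55 rose and 170 fell by at least 1. The median change of the tested genes was -0.15. With median-of-ratios scaling 503 were higher and 595 lower (563 and 568 with quantile normalization). These fits leave the 48 h libraries unpaired. With a replicate block within each time, chosen after seeing the data, 1416 genes changed, 1025 of them among the 1053 and in the same direction. Of 24 gene lists fixed beforehand 3 passed the threshold. Of 10 splits of the 48 h libraries, the real one included, 4 gave at least 3 lists, with 5 the highest of the others. The number of lists therefore did not set the real grouping apart. Among 18 chaperone and heat shock protease genes 0 rose, 8 fell and 10 were not called, and the list median lay 0.17 below that of the tested genes, at -0.32 (camera adjusted p = 0.00146, and adjusted p = 0.21 with an estimated correlation). Adjusted over the list alone, 12 were called. With median-of-ratios scaling 4 fell. The largest falls were those of the disaggregase gene clpB (alr5084, -1.85 ± 0.087, adjusted p = 1.58e-10) and of dnaK (alr1742, -1.32 ± 0.0535, adjusted p = 2.56e-11), and the co-chaperonin gene groES (alr3661) changed by -0.37 (adjusted p = 0.000294, and 0.357 with median-of-ratios scaling). The list's call was also lost with median-of-ratios scaling (adjusted p = 0.132) and with quantile normalization (adjusted p = 0.111).

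Of 29 photosystem II genes 2 rose and 0 fell at 48 h (0 and 1 with FPKM rescaled to a common sum), 0 adjusted over the list alone, with a median 0.22 above that of the tested genes (adjusted p = 0.0418, and adjusted p = 0.363 with an estimated correlation). This call was lost with FPKM rescaled to a common sum (adjusted p = 0.104), with median-of-ratios scaling (adjusted p = 0.0842) and with quantile normalization (adjusted p = 0.42). Of 53 ribosomal protein genes 5 rose and 2 fell (8 and 0 with median-of-ratios scaling), 7 adjusted over the list alone, with a median 0.15 above (adjusted p = 0.00697, lost with quantile normalization at adjusted p = 0.227 and with an estimated correlation at adjusted p = 0.281). The ribosomal call was lost without replicate 3 without cobalt (adjusted p = 0.0534) or replicate 1 with cobalt (adjusted p = 0.123), and the photosystem II call in 4 of the 18 fits that left out a library (replicates 2 and 3 without cobalt, adjusted p = 0.0521 and 0.0611, and replicates 1 and 3 with cobalt, adjusted p = 0.107 and 0.0834). Of 9 ATP synthase genes 0 rose and 0 fell at 48 h, with a median 0.20 above (adjusted p = 0.0783). This list passed with a replicate block within each time, chosen after seeing the data (adjusted p = 0.0335).

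Among the genes fixed in advance for photosynthesis and nitrogen fixation, apcA (alr0021), for the phycobilisome protein allophycocyanin, rose by 0.64 ± 0.144 (adjusted p = 0.0048), with its call lost under median-of-ratios scaling (adjusted p = 0.0528), and rbcL (alr1524), for the large subunit of Rubisco, rose by 0.51 ± 0.108 (adjusted p = 0.00314, and 0.516 with quantile normalization). The nitrogen regulator gene ntcA (alr4392) fell by 0.73 ± 0.17 (adjusted p = 0.00599) and hetR (alr2339), the regulator of heterocyst formation, fell by 0.44 ± 0.0789 (adjusted p = 0.000799, and 0.0888 with median-of-ratios scaling). psaA (alr5154) and psbB (all0138), for core proteins of photosystems I and II, were at -0.06 and 0.12 (adjusted p = 0.689 and 0.391), psaA at 0.11 with median-of-ratios scaling and at -0.21 with quantile normalization (adjusted p = 0.0207). cpcB (alr0528) was at 0.49 (adjusted p = 0.0836, and adjusted p = 0.0297 with the replicate number as a block). The nitrogenase gene nifH (all1455) stood at 2.01 ± 0.391 and 3.26 ± 0.939 FPKM (adjusted p = 0.0836, and 0.044 without replicate 1 with cobalt), and the heterocyst genes hglT (all5341) and devA (alr3712) stood below 4 FPKM in both groups (adjusted p = 0.879 and 0.279).

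At 72 h the genes furthest below their level with cobalt were fldA and all4003. fldA (alr2405), for the flavodoxin that can stand in for ferredoxin under iron shortage, was at 1.26 ± 0.673 FPKM without cobalt and 130.1 ± 22.8 FPKM with cobalt (-5.88 ± 0.282, adjusted p = 1.5e-10). The gene all4003 was at 0.809 ± 0.263 and 106.2 ± 3.57 FPKM (-5.90 ± 0.128, adjusted p = 1.95e-14), and fhuB (all0387), named for a permease of iron-siderophore uptake, changed by -2.13. The plasmid genes stayed lower, with sigB at -4.79, rppA (all7606) at -4.26, rppB (all7605) at -3.58 and rppB (all7583) at -2.09, as did thrS (-3.32), hemB (-2.78) and folE (-2.19).

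Higher without cobalt at 72 h were alr1577 (4.13 ± 0.251, adjusted p = 2.9e-09), alr1578 (3.88 ± 0.213, adjusted p = 7.84e-10) and iolE (alr1580, 3.31 ± 0.227, adjusted p = 1.34e-08), a gene named for an enzyme of inositol breakdown, all in the same run of neighbouring genes. vgrG rose by 1.68 ± 0.0859 (adjusted p = 3.41e-10). The plastocyanin gene petE (all0258), for a copper protein of photosynthetic electron transport, rose from 1117 ± 81.9 to 2563 ± 432 FPKM (1.19 ± 0.125, adjusted p = 2.46e-06). Further rises were those of sixA (alr0221, 1.21), holA (1.20), urtA (1.18), hpsU (alr3178, 0.93), crtH (0.93), urtD (all1948, 0.88) and ntrB (alr0609, 0.79). The call of urtD was lost without replicate 1 without cobalt (adjusted p = 0.0523) or replicate 1 with cobalt (adjusted p = 0.0572).

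At 72 h 1342 genes changed, 379 higher and 963 lower, with 91 rising and 286 falling by at least 1. The median change was -0.09. With median-of-ratios scaling 761 were higher and 854 lower (890 and 779 with quantile normalization). Of the 24 lists 7 passed. Of 19 nitrogen assimilation genes 10 rose, 1 fell and 8 were not called, 12 adjusted over the list alone, with a median 0.61 above that of the tested genes (adjusted p = 5.08e-06, and adjusted p = 0.0676 with an estimated correlation). The risers included the nitrate uptake and reduction genes alr0607 (0.86), alr0608 (0.82) and alr0610 (0.82) and the urea transporter gene urtA, and the member that fell was ntcA (-0.51 ± 0.17, adjusted p = 0.0403, and as high as 0.172 with replicate 3 without cobalt left out). The genes alr0607, alr0608 and alr0610 lie in 1 run of 8 neighbouring higher genes, so they are not independent results. Of 53 ribosomal protein genes 15 rose and 0 fell, 22 adjusted over the list alone, with a median 0.26 above (adjusted p = 5.08e-06, and adjusted p = 0.0676 with an estimated correlation).

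Of 29 photosystem II genes 7 rose and 1 fell at 72 h (4 and 1 with FPKM rescaled to a common sum), 9 adjusted over the list alone, with a median 0.27 above (adjusted p = 0.000578, lost with quantile normalization at adjusted p = 0.0508 and with an estimated correlation at adjusted p = 0.114). The named members were psbA (alr4866, 0.54 ± 0.0753, adjusted p = 4.8e-05), psbV (all0259, 0.43) and psbA (alr4592, 0.31, lost with median-of-ratios scaling at adjusted p = 0.0699), and the psbA copies, which encode nearly the same D1 protein, may share reads, which was not tested here, and are uncertain one by one. Of 18 chaperone genes 9 fell and 0 rose (5 and 0 with median-of-ratios scaling, 5 and 1 with quantile normalization), 10 adjusted over the list alone, with a median 0.17 below (adjusted p = 0.00288, lost with median-of-ratios scaling at 0.252, with quantile normalization at 0.166 and with an estimated correlation at adjusted p = 0.089). Among 4 sigma factor and RNA polymerase genes 2 fell, sigB and rpoD (all5263, -0.66 ± 0.0617), and 0 rose, 2 adjusted over the list alone, and sigC (all1692) was at -0.21 (adjusted p = 0.415). The list's median lay 0.34 below (adjusted p = 0.0202, lost with median-of-ratios scaling at 0.0762, with quantile normalization at 0.0508, in a fit of the 72 h libraries alone at 0.0586 and with an estimated correlation at adjusted p = 0.0884).

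Of 9 ATP synthase genes 0 rose and 0 fell at 72 h (2 and 0 with median-of-ratios scaling), 0 adjusted over the list alone, with a median 0.26 above (adjusted p = 0.0202, lost with median-of-ratios scaling at 0.0762, with quantile normalization at 0.266 and with an estimated correlation at adjusted p = 0.0884). Of 15 genes of the cytochrome b6f complex and soluble carriers 2 rose, petE and petA (all2452, 0.27, lost with FPKM rescaled to a common sum at adjusted p = 0.0641), and 1 fell (4 and 1 with median-of-ratios scaling, 1 and 1 with FPKM rescaled to a common sum), 4 adjusted over the list alone, while petD (alr3422) was at 0.27 (adjusted p = 0.0542). This list's median lay 0.27 above (adjusted p = 0.0446, and adjusted p = 0.339 with an estimated correlation). Its call was lost with FPKM rescaled to a common sum (adjusted p = 0.0516), with median-of-ratios scaling (adjusted p = 0.0863) and with quantile normalization (adjusted p = 0.17). It was also lost without replicate 3 without cobalt (adjusted p = 0.0594), replicate 1 with cobalt (adjusted p = 0.063) or replicate 3 with cobalt at 96 h (adjusted p = 0.052).

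Among the fixed genes at 72 h, apcA rose by 0.57 ± 0.144 (adjusted p = 0.00841, and 0.0807 with median-of-ratios scaling), psbB rose by 0.27 ± 0.0838 (adjusted p = 0.0297, lost without any one of the 6 libraries of this time, at adjusted p between 0.053 and 0.1, at 0.0568 with FPKM rescaled to a common sum, 0.18 with median-of-ratios scaling and 0.746 with quantile normalization), and hetR fell by 0.31 ± 0.0789 (adjusted p = 0.00771, 0.194 with median-of-ratios scaling and 0.331 with quantile normalization). rbcL (0.08), psaA (-0.06), cpcB (0.47), nifH (all1455, -0.17), hglT (-0.12) and devA (-0.03) did not pass the threshold. psaA was at 0.055 with median-of-ratios scaling and passed with quantile normalization (-0.18, adjusted p = 0.0425).

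At 96 h all4003 and fldA again showed the largest falls. all4003 was at 1.35 ± 0.241 FPKM without cobalt and 298.3 ± 26.1 FPKM with cobalt (-7.00 ± 0.128, adjusted p = 1.93e-15), and fldA at 2.62 ± 1.15 and 348.9 ± 113 FPKM (-6.59 ± 0.282, adjusted p = 2.49e-11). sigB changed by -4.09, rppA by -4.79 (all7606) and -1.99 (all7584), rppB by -3.50 (all7605) and -1.91 (all7583), and fhuB by -2.27. The psbA copies alr4592 and alr3727 were lower, alr4592 at 303.7 ± 14.8 against 1162 ± 85.3 FPKM (-1.93 ± 0.0622, adjusted p = 1.01e-12) and alr3727 at 363.9 ± 18 against 1142 ± 84.1 FPKM (-1.65 ± 0.0606, adjusted p = 4.64e-12), with the same uncertainty. alr1578 reached 222.3 ± 19.7 against 6.94 ± 1.16 FPKM (4.82 ± 0.213, adjusted p = 3.58e-11), alr1577 rose by 4.57 and iolE by 4.37.

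bchL (all5078), for a subunit of the light-independent protochlorophyllide reductase of chlorophyll synthesis, rose at 96 h from 325.5 ± 9.8 to 621.9 ± 45.3 FPKM (0.93 ± 0.0936, adjusted p = 1.14e-06). Other rises were those of urtA (1.41), urtD (1.07), sixA (1.03), ntrB (all3335, 0.89), vgrG (0.84), holA (0.80), leuB (alr1313, 0.77) of leucine synthesis and rplB (0.77). The call of ntrB (all3335, adjusted p = 0.0253) was lost without replicate 1 or 2 without cobalt (adjusted p = 0.103 and 0.0819) or replicate 2 or 3 with cobalt (adjusted p = 0.0837 and 0.0584).

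At 96 h 1545 genes changed, 410 higher and 1135 lower, with 73 rising and 332 falling by at least 1. The median change was -0.14. With median-of-ratios scaling 880 were higher and 853 lower (1057 and 862 with quantile normalization). In a fit of the 96 h libraries alone 908 genes changed. Of the 24 lists 4 passed, and all 4 also passed with an estimated correlation. Of 10 splits of the 96 h libraries, the real one included, 6 gave at least 4 lists, with 10 the highest of the others. The number of lists therefore did not set the real grouping apart. Of 18 chaperone genes 1 rose and 7 fell, with a median at -0.060 relative to that of the tested genes. The chaperone list did not pass at 96 h (adjusted p = 0.565, and adjusted p = 3.52e-05 with fry, downward). Of 19 nitrogen assimilation genes 9 rose and 1 fell, 12 adjusted over the list alone, with a median 0.59 above that of the tested genes (adjusted p = 2.37e-06), among them alr0612 (0.81 ± 0.0743, adjusted p = 3.66e-07), alr0610 (0.65) and alr0608 (0.57). Of 53 ribosomal protein genes 11 rose and 3 fell (18 and 0 with median-of-ratios scaling, 21 and 0 with quantile normalization), 14 adjusted over the list alone, with a median 0.30 above (adjusted p = 7.68e-07), among them rplB (0.77), rplN (all4205, 0.46) and rplV (all4210, 0.41).

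Of 7 genes of Rubisco, the carboxysome and inorganic carbon uptake 5 rose and 0 fell at 96 h, 5 adjusted over the list alone, with a median 0.65 above (adjusted p = 0.000955, lost with quantile normalization at 0.0952). Of these genes 2 rose with FPKM rescaled to a common sum and 3 with quantile normalization. rbcL rose by 0.61 ± 0.108 (adjusted p = 0.000386), alr1526 by 0.56 ± 0.189 (adjusted p = 0.0385, lost with FPKM rescaled to a common sum at 0.0723 and with quantile normalization at 0.0998, and as high as 0.137 with replicate 1 without cobalt left out) and alr2877 by 0.48 ± 0.121 (adjusted p = 0.00764). At 48 h this list did not pass, with 1 gene higher and 1 lower and a median 0.35 above (adjusted p = 0.227). Nor did it at 72 h, with 0 higher and 2 lower and a median 0.21 below (adjusted p = 0.307, and adjusted p = 1.68e-05 with fry, downward). Of 9 ATP synthase genes 4 rose and 0 fell, 5 adjusted over the list alone, with a median 0.39 above (adjusted p = 0.00304, lost with quantile normalization at 0.121), among them atpH (all0006, 0.42), atpA (all0005, 0.30) and all0007 (0.25, lost with median-of-ratios scaling at adjusted p = 0.0553). Of 29 photosystem II genes 5 rose and 6 fell at 96 h, 11 adjusted over the list alone, and the list did not pass (adjusted p = 0.887). Its median lay at 0.049 and its mean at -0.22, and fry gave adjusted p = 0.00071, downward.

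Among the fixed genes at 96 h, apcA rose by 0.61 ± 0.144 (adjusted p = 0.00421) and psbB rose by 0.32 ± 0.0838 (adjusted p = 0.00827, and 0.0743 with median-of-ratios scaling and 0.0521 with quantile normalization). ntcA was at -0.45 (adjusted p = 0.0648, and 0.0162 without replicate 1 without cobalt). It passed at -0.27 with median-of-ratios scaling (adjusted p = 0.0328) and -0.26 with quantile normalization (adjusted p = 0.0479). With the deposited values hetR (-0.08), psaA (0.00), cpcB (0.44), nifH (all1455, -0.02), hglT (-0.21) and devA (0.11) did not pass. With quantile normalization cpcB (0.47, adjusted p = 3.22e-06) and psaA (-0.19, adjusted p = 0.0262) did. Lists of heterocyst regulators, heterocyst glycolipid genes, heterocyst envelope genes, nitrogenase genes, photosystem I genes, phycobilisome genes and cobalamin synthesis genes passed at none of the 3 times by camera, with adjusted p between 0.262 and 0.993. The fixed genes nifH (all1455), hglT and devA stood below 4 FPKM in every group. There the log2(FPKM + 1) scale understates changes, so a change could be missed. Fry, which does not compare a list with other genes, called the heterocyst regulators downward at 48 and 96 h (adjusted p = 0.0434 and 0.0228). Their medians lay at 0.0076 and -0.077 relative to that of the tested genes, which was itself below 0. Fry also called the heterocyst glycolipid and nitrogenase genes downward at 96 h (adjusted p = 0.0396 and 0.000797), with medians at -0.038 and -0.044 relative to that of the tested genes. These fry calls therefore do not set the lists apart from the other genes. The phycobilisome genes were called downward by fry at 72 and 96 h (adjusted p = 0.00722 and 0.0228), with medians of 0.17 and 0.21 and means of -0.070 and -0.051. Single members of these lists were called. Of 12 phycobilisome genes 2 rose and 3 fell at 48 h, 3 rose and 4 fell at 72 h, and 4 rose and 4 fell at 96 h, with 8, 10 and 10 adjusted over the list alone (1 and 1, 1 and 3, and 5 and 3 with median-of-ratios scaling). Of 13 heterocyst regulator genes 4 fell at 48 h, 1 rose and 4 fell at 72 h, and 3 fell at 96 h (0 and 2, 1 and 3, and 1 and 2 with median-of-ratios scaling). Of 17 cobalamin synthesis genes 3 fell at 48 h, 2 fell at 72 h, and 1 rose and 4 fell at 96 h. These counts were 0 and 0, 1 and 1, and 2 and 2 with median-of-ratios scaling and 0 and 0, 1 and 1, and 4 and 2 with quantile normalization. The heterocyst glycolipid, heterocyst envelope and nitrogenase lists had 1 or 2 called members at each time as deposited and 0 to 3 with the other scalings. Of 13 photosystem I genes 0 were called at any time as deposited and 0 or 1 with the other scalings. Over all lists the adjusted p of those that did not pass ran from 0.0783 to 0.899 at 48 h, from 0.0672 to 0.993 at 72 h and from 0.0969 to 0.936 at 96 h.

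**Figure D2:**
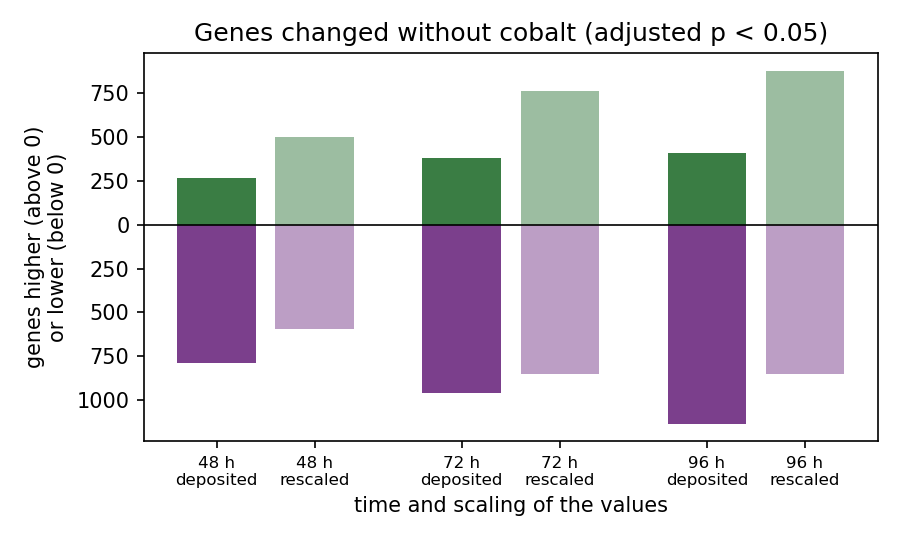
Number of genes higher (bars above 0) or lower (bars below 0) without cobalt at adjusted p under 0.05, at 48, 72 and 96 h (horizontal axis), for FPKM as deposited and after median-of-ratios scaling (paler bars, marked rescaled). At 96 h the split is 410 higher and 1135 lower as deposited and 880 and 853 after rescaling.

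**Figure D3:**
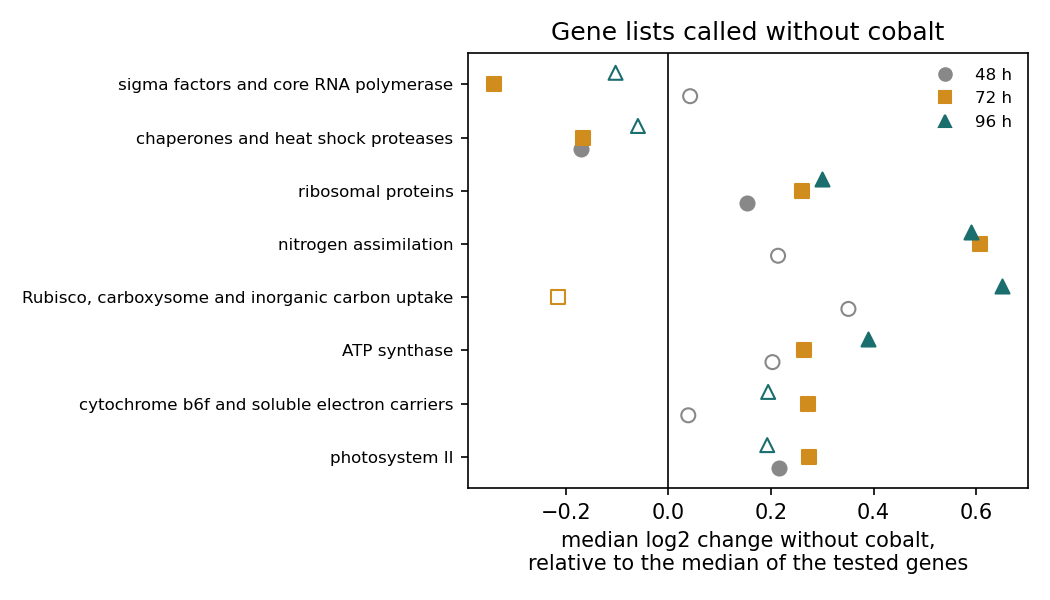
Median log2 change without cobalt of the gene lists called at 1 time or more, relative to the median of the tested genes (horizontal axis), at 48, 72 and 96 h. Filled symbols passed the camera threshold with the preset correlation and open symbols did not. Nitrogen assimilation lies at 0.61 at 72 h and 0.59 at 96 h.

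The genes called at each time overlapped. At 48 and 72 h 177 genes were higher at both and 541 lower at both, where independent lists of these sizes would share 17.6 and 132. At 72 and 96 h 212 were higher at both and 568 lower at both, where independent lists would share 27.1 and 191. At all 3 times 129 genes were higher and 366 lower, among them sigB, rppA (all7606), thrS and hemB on the lower side and alr1577, alr1578, urtA, vgrG and holA on the higher side. Each time had its own libraries with cobalt.

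Whether the effect of cobalt removal differed between times was tested as the difference of the effects. From 48 to 72 h it became more negative for fldA (-4.02 ± 0.399, adjusted p = 1e-05), and fhuB (-1.54), glgP (all2806, -1.05 ± 0.111, adjusted p = 1.68e-05), for glycogen phosphorylase, and devH itself (-0.99 ± 0.126, adjusted p = 0.000107) moved the same way. It became more positive for rppA (all7606, 1.96 ± 0.207, adjusted p = 1.68e-05), iolE (1.68 ± 0.321, adjusted p = 0.00443, lost with a pseudocount of 0.1 at 0.0758), rppA (all7584, 1.38) and petE (1.36). For the plasmid genes a positive difference means a smaller fall at 72 h than at 48 h. At 72 h glgP was at 18.9 ± 0.538 FPKM without and 25.8 ± 1.31 FPKM with cobalt. On the log2 scale that is less than the change of its effect, so glgP was higher without cobalt at 48 h and its direction turned. In all 232 genes differed between 48 and 72 h, 77 more positive and 155 more negative.

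From 48 to 96 h 577 genes differed, 230 more positive and 347 more negative as deposited, and 365 and 352 with median-of-ratios scaling. The differences were -4.72 ± 0.399 for fldA (adjusted p = 4.06e-07), -2.71 ± 0.227 for nifH (alr0874, adjusted p = 3.8e-07), -2.13 ± 0.088 for psbA (alr4592) and -1.81 ± 0.0857 for psbA (alr3727). More positive were iolE (2.73 ± 0.321, adjusted p = 1.75e-05), bchL (2.27 ± 0.132, adjusted p = 5.61e-09), hemB (all4725, 2.197 ± 0.187) and thrS (1.82 ± 0.153). The effect on bchL was -1.34 at 48 h, -0.67 at 72 h and 0.93 at 96 h, so its direction turned. That on nifH (alr0874) was 1.14 at 48 h and -1.57 at 96 h, at levels of 2.79 ± 0.0497 and 10.3 ± 1.17 FPKM at 96 h. The smaller effect on hemB at 96 h went with a lower level with cobalt, 12.4 ± 0.732 FPKM against 95.8 ± 7.14 FPKM at 48 h.

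**Figure D4:**
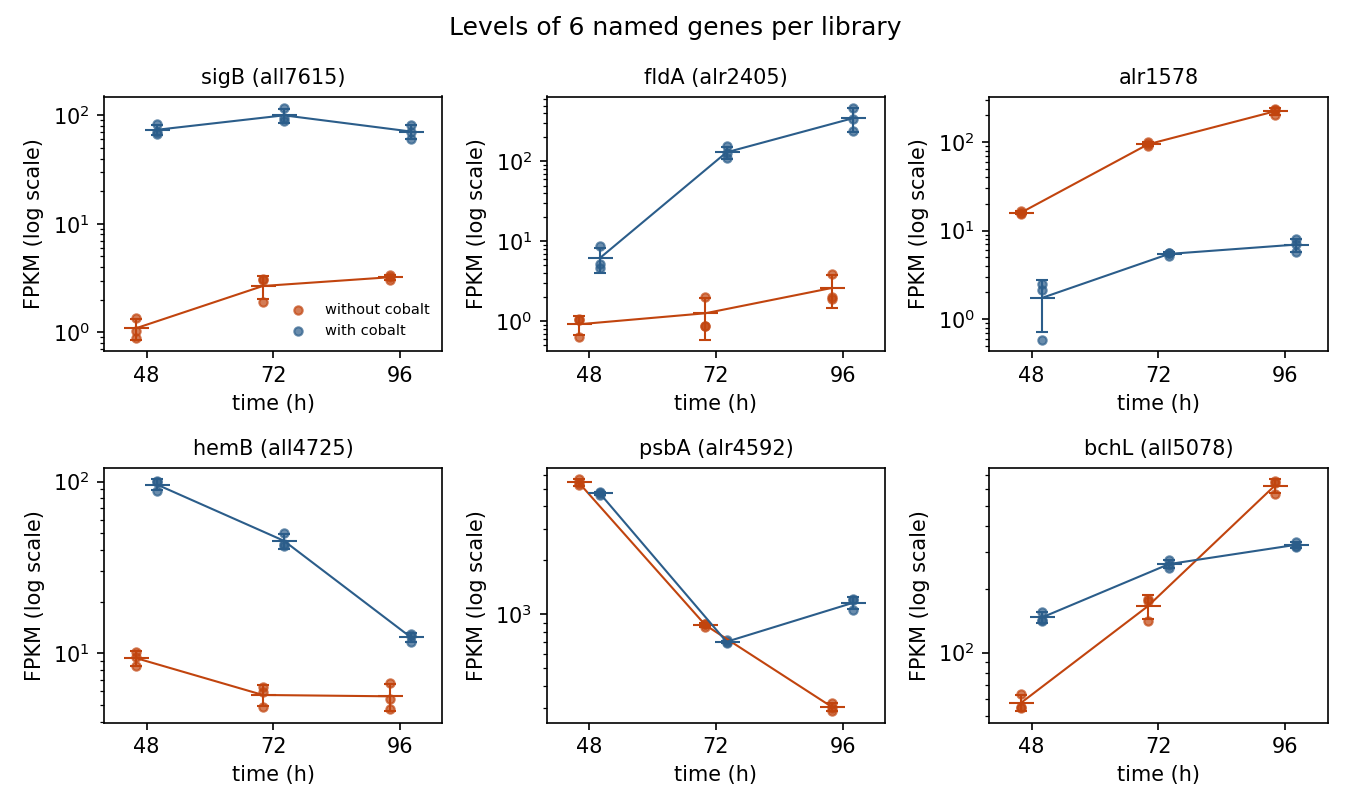
FPKM on a log scale (vertical axes) against time in hours for sigB, fldA, alr1578, hemB (all4725), psbA (alr4592) and bchL without cobalt and with cobalt. Points are libraries, and marks with bars give the mean and SD of 3 libraries joined by lines. With cobalt, fldA goes from 6.16 FPKM at 48 h to 348.9 FPKM at 96 h.

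Culture age was compared within the cultures with cobalt. At 72 h against 48 h fldA rose from 6.16 ± 2.17 to 130.1 ± 22.8 FPKM (4.22 ± 0.282, adjusted p = 1.29e-08), ppsA, for phosphoenolpyruvate synthase, by 1.65 and ntrB (alr2878) by 1.54. The photosystem II genes psb34 (-4.31 ± 0.215, adjusted p = 3.32e-10), psbA (all3572, -3.01 ± 0.0695) and psbA (alr3727, -2.88 ± 0.0606) fell, the last from 5043 ± 75.8 to 684.5 ± 17.2 FPKM. In all 1512 genes changed, 890 higher and 622 lower at 72 h as deposited. The split was 1000 and 864 with median-of-ratios scaling and 953 and 980 with quantile normalization.

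At 96 h against 48 h fldA rose by 5.60 ± 0.282 (adjusted p = 2.13e-10), ppsA by 2.86 ± 0.102 (adjusted p = 4.01e-12) and nifH (alr0874) by 2.03 ± 0.161 (adjusted p = 4.79e-08). folE (all4721) fell by 3.13 ± 0.243, hemB (all4725) fell by 2.85 ± 0.132 and psb34 fell by 2.70 ± 0.215. In all 2797 genes changed, 2300 higher and 497 lower at 96 h. The median change of the tested genes was 0.36. With median-of-ratios scaling 1229 were higher and 1260 lower.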

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

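The tests of explanations for the plasmid run, the age-related genes, the direction of the calls and the genes next to devH were chosen after the results were seen, and the splits of the libraries were planned.

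The effect of cobalt removal differed between times for 232 genes from 48 to 72 h and 577 genes from 48 to 96 h, by the limma test of the difference. The genes named for the first difference were rppA (all7606, 1.96), iolE (1.68), rppA (all7584, 1.38), petE (1.36), devH (-0.99), glgP (-1.05), fhuB (-1.54) and fldA (-4.02). For the difference from 48 to 96 h they were iolE (2.73), bchL (2.27), hemB (all4725, 2.197), thrS (all4723, 1.82), devH (-0.78), psbA (alr3727, -1.81 and alr4592, -2.13), nifH (alr0874, -2.71) and fldA (-4.72). These are the genes the naming rule took for the differences, with devH added, and other genes named in the report, such as all4003 and clpB, also passed this test at 96 h.

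Among 100 splits of the 12 libraries within each time, the real one included, 5 gave at least 232 genes for the difference from 48 to 72 h, with 483 the highest of the others, and 5 gave at least 577 for that from 48 to 96 h, with 1307 the highest. The 4 other splits behind the first count exchanged 2 libraries per group at one time and none at the other. Of the 4 behind the second count, 2 exchanged 2 libraries per group at 48 h and 0 at 96 h, and 2 exchanged 1 at 48 h and 2 at 96 h. Unequal exchange at the 2 times turns the effect shared by both times into an apparent difference. Such splits are no measure of chance for a difference between times, so they neither exclude chance nor speak for it. For the counts at a single time the 6 libraries allow 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with as many genes at 48 h (1053), 72 h (1342) and 96 h (1545) and for age at 72 h (1512) and 96 h (2797), and the highest of the others was 0 in each. For the gene lists 4 of 10 splits gave at least the real 3 at 48 h (highest other 5), 1 of 10 the real 7 at 72 h (highest other 4) and 6 of 10 the real 4 at 96 h (highest other 10). So the numbers of lists at 48 and 96 h did not set the real grouping apart from other splits.

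The first pattern is the fall of 38 neighbouring genes on pCC7120beta, with a median of -3.45 at 48 h. Loss of the whole plasmid is argued against. The 92 tested genes of the plasmid outside this run and a shorter one had a median of -0.28 and a lower quartile of -0.52 at 48 h. The run's upper quartile was -2.02, but both sets were chosen on the 48 h calls, which itself sets them apart. In the 72 h libraries, which did not define the sets, the other genes had a median of -0.39 and a lower quartile of -0.57. The run's upper quartile there was -1.72. Loss or rearrangement of the run's segment alone was not tested. A fall in step with the devH difference is argued against too, over the plasmid's lower runs as chosen at 72 h. The devH difference grew at 72 h, while the effect on these genes became smaller, by a median of 0.58 (quartiles 0.22 and 1.37, 16 of 44 genes called). That choice works against a smaller effect. From 48 to 72 h devH rose from 600.6 to 973.4 FPKM with cobalt and fell from 295.8 to 240.7 FPKM without it. A dependence on devH that is not in step with its transcript was not tested. Whether the run responds to cobalt itself or to devH cannot be told apart, because the 18 libraries change both together, at the median of -3.45. A direct response to cobalt, or a dependence on devH not in step with its transcript, may account for the run's fall. These are hypotheses that a strain with cobalt-independent devH could test.

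The second pattern is a set of 46 genes that rose by at least 3 from 48 to 96 h with cobalt, with a median of 3.71. Culture age alone is argued against as an account of the set's median. Without cobalt the same genes had a median of 0.19 and an upper quartile of 1.24, although they were chosen on the libraries with cobalt. Many of them lie in the runs from all2631 to alr2683 and from alr3997 to all4003, and such neighbours are not independent results. Members there, such as all2676 (-0.095) and all4003 (0.19), were near 0 without cobalt and weigh on the median. Of the 46 genes 12 rose by at least 1 without cobalt, among them asl0597 (2.53). For the 5 genes whose difference was not called, all3232 (3.61 with and 3.39 without cobalt), alr4525, alr4529, asr1134 and PCC7120DELTA_RS14235, age alone stays open, with medians of 3.23 with and 2.53 without cobalt, because they were picked for the missing call. With median-of-ratios scaling the median rise was 3.33. That scaling moved the median change of the tested genes only from 0.36 to -0.0024, so genes chosen for a rise of at least 3 had to keep most of it. The outcome was thus fixed by the choice of genes and is no separate test of the scaling. Whether cobalt or devH is needed for the rise cannot be told apart in this design, where the median of 3.71 belongs to cultures with both.

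The third pattern is the excess of lower over higher calls without cobalt. With median-of-ratios scaling the share of higher calls was 45.8% at 48 h, 47.1% at 72 h and 50.8% at 96 h, against 25.3%, 28.2% and 26.5% as deposited. That scaling brings the median change close to 0, which makes a near-even split, so these shares do not decide whether the scaling of the deposited values gives the excess, and this stays open. Less messenger RNA per cell without cobalt could also give a median such as the -0.14 at 96 h, and stays open because no added standard is among the values used.

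The genes next to devH did not follow it. The lowest change among the 6 neighbours at 72 h was -0.45, none of them was called at 48 or 72 h, and alr3950 fell by 0.59 at 96 h (limma adjusted p = 0.0012).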

How the results depend on the processing

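The array weights estimated gene by gene and the replicate block within each time were chosen after seeing the data, and the other settings were planned. Pseudocounts, filters and rescaling to a common sum left each count of genes within 1.5 times its reported value, and devH kept its exact permutation p of 0.00025 under all settings run on it, with log2 differences from -1.66 to -1.46. Default array weights gave 2298, 2812 and 5170 genes at 48, 72 and 96 h, 1266 and 2640 for the differences between times and 2943 and 4605 for age, but gave replicate 2 without cobalt and replicate 3 with cobalt at 96 h weights of 152.9 and 47.7, so these counts rest on few libraries. Weights estimated gene by gene gave 2016, 2385, 3647, 836, 1846, 2806 and 4252. Requiring a change of at least 1 gave 225, 377, 405, 128, 281, 390 and 847. Fitting only the groups compared gave 908 genes at 96 h and 5 lists at 48 h. Lists past the threshold at 48, 72 and 96 h numbered 1, 3 and 4 with median-of-ratios scaling, 0, 2 and 2 with quantile normalization, 0, 0 and 4 with an estimated correlation and 10, 16 and 15 with fry, which did not call photosystem II (0.451) or ribosomal proteins (0.134) at 48 h. ATP synthase (0.0385) and nitrogen assimilation (0.0415) also passed at 48 h in the fit of the compared groups alone, and carbohydrate catabolism (0.0399) at 72 h with FPKM rescaled to a common sum. A filter at 10 FPKM ended the photosystem II call at 48 h (0.0552) and added carotenoid synthesis at 72 h (0.039) and cytochrome b6f (0.0358) and chlorophyll synthesis (0.04) at 96 h. The replicate block gave 1249, 1592 and 1760 genes at 48, 72 and 96 h, 269 and 686 for the differences, 1740 and 3075 for age and 3, 7 and 4 lists. It added calls for cpcB at each time (adjusted p = 0.0297, 0.0296 and 0.0351) and for ntcA at 96 h (0.0388) and changed no other named gene's call. A block within each time gave 1416, 1780 and 1971 genes, 282 and 740 for the differences and 4, 7 and 4 lists, with ATP synthase added at 48 h (0.0335). It added the same gene calls, for cpcB (0.0188, 0.0187 and 0.0221) and ntcA at 96 h (0.0237), and one for petD at 72 h (0.0418). Leaving out each library gave 741 to 1133 genes at 48 h, 1069 to 1450 at 72 h, 1190 to 1628 at 96 h, 172 to 260 and 463 to 640 for the differences and 1138 to 1600 and 1967 to 3106 for age, with 1 to 4, 6 to 8 and 4 to 6 lists and devH between -1.63 and -1.58. The 1967 came without replicate 1 with cobalt at 96 h, and a single list at 48 h came without replicate 3 without cobalt. Leaving out replicate 1 with cobalt at 48 h also ended both the photosystem II and the ribosomal call (adjusted p = 0.107 and 0.123). Without the library with the conflicting treatment label 1353 genes changed at 96 h, and no named gene lost its call.

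For the 148 named gene results, 978 of 1024 values under other settings and 2607 of 2664 with a library left out kept direction and side of the threshold. The other settings here were the pseudocounts, the scalings and the replicate blocks, the block within each time leaving out culture age. The filters, the array weights and the fits of the compared groups alone were not followed gene by gene. Values that changed sign were small. They were psaA (0.11 at 48 h and 0.055 at 72 h with median-of-ratios scaling, -0.033 at 96 h rescaled to a common sum and -0.19 with quantile normalization, adjusted p = 0.0262), devA at 72 h (0.056 and 0.086 with median-of-ratios scaling and quantile normalization), nifH (all1455) at 96 h (0.068 and 0.17), hetR at 96 h (0.095 and 0.041) and hglT with quantile normalization (0.059 at 72 h and 0.022 at 96 h). With a library left out psaA ranged from -0.12 to 0.011 at 48 h and from -0.054 to 0.065 at 96 h, hglT from -0.016 to 0.17 at 48 h, devA from -0.16 to 0.17 at 72 h and from -0.12 to 0.27 at 96 h, and nifH from -0.12 to 0.088 at 96 h. The cause was not tested. The calls of lpxB at 48 h were lost without replicate 2 or 3 without cobalt (adjusted p = 0.169 and 0.0764), without each library with cobalt (0.153, 0.0706 and 0.0634), and without replicate 2 without cobalt at 96 h (0.051) or replicate 3 with cobalt at 72 h (0.052). That of ntcA at 72 h was lost without replicates 1 and 3 without cobalt (0.0672 and 0.172), 2 and 3 with cobalt (0.155 and 0.0811) and 4 libraries of other times (0.0503 to 0.0528). Calls were gained for cpcB at 48 h without replicate 1 without cobalt (0.0264) and at 96 h without replicate 1 without cobalt (0.0369) or replicate 2 with cobalt (0.0363), and for petD at 72 h without replicate 3 without cobalt (0.0391) or any of 4 libraries of other times (0.0253 to 0.0427). Depth is unknown, so how far it limits low genes cannot be stated.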

Other observations

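The search for runs of neighbouring genes, with its tests, was chosen after the data were seen. Runs of at least 5 neighbouring tested genes called in the same direction numbered 11 at 48 h, 21 at 72 h and 22 at 96 h, where 100 shuffles of gene order gave at most 3, 3 and 6. The longest run at 48 h was the 38 genes of pCC7120beta from all7583 to alr7622. Of the 137 tested genes of that plasmid 59 were lower at 48 h, 38 of them in that run and 7 in a shorter one, and 14 among the 92 genes outside both. On pCC7120alpha 41 of 375 genes were higher and 10 lower at 48 h, 39 higher and 26 lower at 72 h, and 67 higher and 23 lower at 96 h.

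On the chromosome the run from alr1576 to alr1580, with iolE, had a median of 2.29 at 48 h, and the run from alr1576 to alr1586 had medians of 2.69 at 72 h and 3.83 at 96 h. The run from all3317 to all3326, with vgrG, was higher by a median of 1.38 at 48 h and 1.54 at 72 h. At 96 h the run from all3317 to all3327 was higher by a smaller median of 0.84. Lower were the run from all0387 to alr0397, with fhuB (-1.997 at 72 h), the run from alr3057 to alr3074, with lpxD (-2.06 at 72 h and -1.93 at 96 h), and 27 genes from all2631 to alr2663 at 96 h (-3.40). At 48 h 5 genes from all2491 to alr2495, which include sufB, sufC and sufD of iron-sulfur cluster assembly and their regulator gene sufR, were lower by a median of -0.57. At 72 h 5 genes from alr4017 to all4021, among them opcA, zwf, tal and fbp of the pentose phosphate pathway and sugar phosphate turnover, were lower by a median of -0.51. Neighbouring genes are often read together in bacteria, so a run is not a set of independent results.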
